A study of Mus musculus with 28 samples.

How the data were processed

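The 28 libraries of mouse blood were grouped by the age the labels give. Per the labels' protocols, libraries were made from total RNA with Illumina's TruSeq RNA Library Prep Kit v2, which keeps no strand. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.4.1d and featureCounts 1.4.6-p4 were used with the mouse build GRCm38, without stated roles, and the annotation release is not given in the sources used here. The deposited count table holds 1 whole-number count per gene and library, for 47729 genes. The deposited second table, named RPKM by the authors, was treated as a score of unknown use and left out: in 1683 genes with over 500 counts in every library its values did not follow each library's own total (median range 1.7 on the log2 scale) but the 28 totals repeated down the rows of the table (largest range 0.00166).

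Symbols, positions and gene types came from the GENCODE M21 annotation of GRCm38, and 505 genes without a symbol held 0.0215% of counts. Genes on opposite strands that overlap cannot be told apart with this kit, and genes with near-identical copies can share or lose reads. The limit that a count of 0 allows is 3 counts of a library's scaled total. Such limits cover counting error only.

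All tests were run in R 4.3.3. Genes passing edgeR's filterByExpr with the 5 ages as groups were kept, 14331 genes with 99.9% of counts. Scaling was by TMM factors, and CPM values are on that scale unless stated. The fit used edgeR 4.0.16 with robust dispersions, 1 coefficient per age over all 28 libraries and 23 residual degrees of freedom, and its quasi-likelihood F-test, which is 2-sided. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called below 0.05. Fold changes are on the log2 scale, with the standard error taken as the fold change over the root of F. The pairs tested were 9, 15, 24 and 30 against 2 months, 15 against 9, 24 against 15 and 30 against 24. Further tests asked whether a gene differed among the 5 ages, had a slope on age in months, or departed from that straight line. Principal components were computed on log2 CPM with a prior count of 2.

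Of 44 lists of marker and pathway genes, 43 had at least 5 members tested. Each was tested against the other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. Counts of a list's genes are given over all genes tested and adjusted over the list alone. Lists overlap in members, and a list stands for transcripts and not for a number of cells. V segment counts of Igkv, Ighv and Trbv were thinned to 5009, 719 and 503 counts, the smallest totals among libraries with at least 100. The inverse Simpson index was averaged over 100 draws in Python 3.11.15 with NumPy 2.4.6, and ages 30 and 2 months were compared by an exact 2-sided permutation test in SciPy 1.17.1.

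Named genes were chosen by rule, leaving out predicted genes, pseudogenes and receptor segments. For 30 against 2 months these are the 8 largest rises and 8 largest falls among called genes with a mean of at least 2 CPM and no overlap between the ages. For other pairs they are the 4 largest of each, for the trend the 6 steepest of each, and for departures the 6 of smallest p. From each list they are up to 3 called members of smallest p, or up to 2 for other pairs where the list was called. Hbb-bs, Alas2, Ms4a1, Cd3e, Cd8a, S100a8, Pf4, Ighm and Cdkn2a are given in any case. A few genes that meet the rule are not named. Genes named for values in 1 library, and Hspa1a and Hspa1b where they head no list, were chosen after their values were seen.

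Groups, tests, lists, the rule for named genes and the alternatives below were fixed before the data were examined, except where said otherwise. The alternatives were DESeq2 size factors in edgeR, haemoglobin genes removed, no filter on low counts, DESeq2 1.42.0, limma voom with quality weights, the haemoglobin share as a covariate, a threshold of 0.01, a fit over the compared ages alone, leaving out each library, log2 of age, no 2 month group, no thinning and the Shannon index. The chosen fit has no covariate, since the labels name no batch.

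Simulated data held 14331 genes, 100 changed 2-fold and 100 4-fold. For 30 against 2 months the pipeline recovered 44 and 99 (4 of 147 calls false). For the trend it recovered 54 and 100 (8 of 162) and for the departure 82 and 100 (8 of 190). With no gene changed edgeR called 0. Whether these rates hold in real data with outlying libraries was not tested.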

Results

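Libraries made from total RNA of whole blood from male C57BL/6 mice were sequenced at 5 ages. The 28 libraries comprised 6, 5, 7, 5 and 5 at 2, 9, 15, 24 and 30 months. Total counts per library ranged from 17076232 to 37838455 (CPM below are counts scaled to a common library size). The labels do not say that each library came from a separate animal, so p-values measure the spread between libraries. Alas2, the erythroid enzyme that starts haem synthesis, held the most counts in 27 of the 28 libraries. It took 16.2% ± 1.87 (SD, n = 6) of counts at 2 months and 13.7% ± 3.83 (SD, n = 5) at 30 months. Haemoglobin genes took 1.26% ± 0.441 (SD, n = 6) and 1.75% ± 1.03 (SD, n = 5), uncertain because near-identical copies can split or lose reads. The library of 15 months replicate 4 lay apart at 213 on the first principal component of log2 CPM (31.2% of the variance), the others between -64.5 and 50.6. Its median Spearman correlation with its own group was 0.807, and Alas2 took 1.14% of its counts. No 2 libraries of 1 age held copied counts (lowest chi-square 16.8 per degree of freedom).

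**Figure D1:**
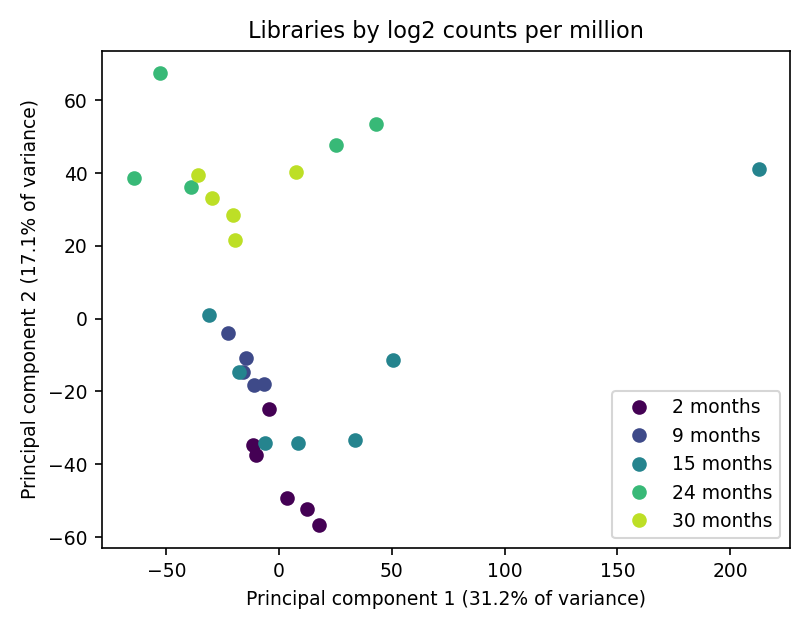
Scores of the 28 libraries on the first and second principal components of log2 CPM; each point is 1 library, coloured by age. The library at 213 on the first is 15 months replicate 4.

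Blood at 30 months was compared with blood at 2 months. By camera with its preset correlation the natural killer cell list was called lower at 30 months, and the cytotoxic lymphocyte, mature neutrophil, classical monocyte, platelet and antioxidant lists higher, and none held with it estimated (adjusted p = 0.253 to 0.611 with an estimated correlation). Mitochondrial ribosomal RNA took 2.14 to 3.8% of counts at 2 months and 3.47 to 8.15% at 30 months. Of 14331 genes tested, 2072 changed at an adjusted p below 0.05 by edgeR's quasi-likelihood test, 878 higher and 1194 lower. In 2494 genes the values of the 5 old and 6 young libraries did not overlap, where 62.0 would by chance. The largest rises (log2 fold change ± SE) among these were in Casp12 (4.21±0.42), Wwtr1 (4.18±0.63), Nbea (4.08±0.60) and Gzmm (3.94±0.58). Gzmm encodes granzyme M. Further rises were in Tspan12 (3.77±0.68), Tm4sf1 (3.60±0.58), Pmp22 (3.30±0.62) and Dmrta1 (3.27±0.62), with adjusted p of these 8 between 2.2e-06 and 0.00174. Casp12 went from 0.407 ± 0.212 CPM (SD, n = 6) to 7.52 ± 3.38 (SD, n = 5).

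The largest falls from 2 to 30 months were led by receptors of natural killer cells. They were Klra4 (-3.23±0.65), Ncr1 (-3.13±0.65), Klri2 (-3.09±0.59) and Klra1 (-2.93±0.65), followed by Klrb1c (-2.66±0.52), Ccr9 (-2.60±0.58), Fcer2a (-2.56±0.83) and Gzma (-2.55±0.41), with adjusted p between 0.000539 and 0.0381. Klra4 and Klra1 encode Ly49 receptors, Ncr1 NKp46, Klrb1c the NK1.1 antigen and Fcer2a the B cell receptor CD23. Ncr1 fell from 29 ± 2.77 CPM (SD, n = 6) to 3.27 ± 2.23 (SD, n = 5). Of the natural killer cell list, 12 of 25 members fell and 1 rose (17 and 1 adjusted over the list alone), with examples Serpinb9b (-1.88±0.30), Gzma and Klri2 (adjusted p = 2.11e-09, adjusted p = 0.253 with an estimated correlation). In the cytotoxic and effector memory lymphocyte list 8 of 30 members rose and 2 fell (11 and 2 adjusted over the list alone). Gzmk rose (3.0±0.47, from 4.12 ± 2.01 to 33 ± 26.8 CPM), as did Gzmm, while Gzma fell (adjusted p = 0.000233, adjusted p = 0.562 with an estimated correlation). The inhibitory receptor and exhaustion list had 3 of 14 members higher (4 adjusted over the list alone): Pdcd1 (2.11±0.44) and Lag3 (2.25±0.51) (Pdcd1 1.52, adjusted p = 0.0247 without 30 months replicate 1), and Casp4 (1.09±0.20) (adjusted p = 0.0159, adjusted p = 0.562 with an estimated correlation).

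**Figure D2:**
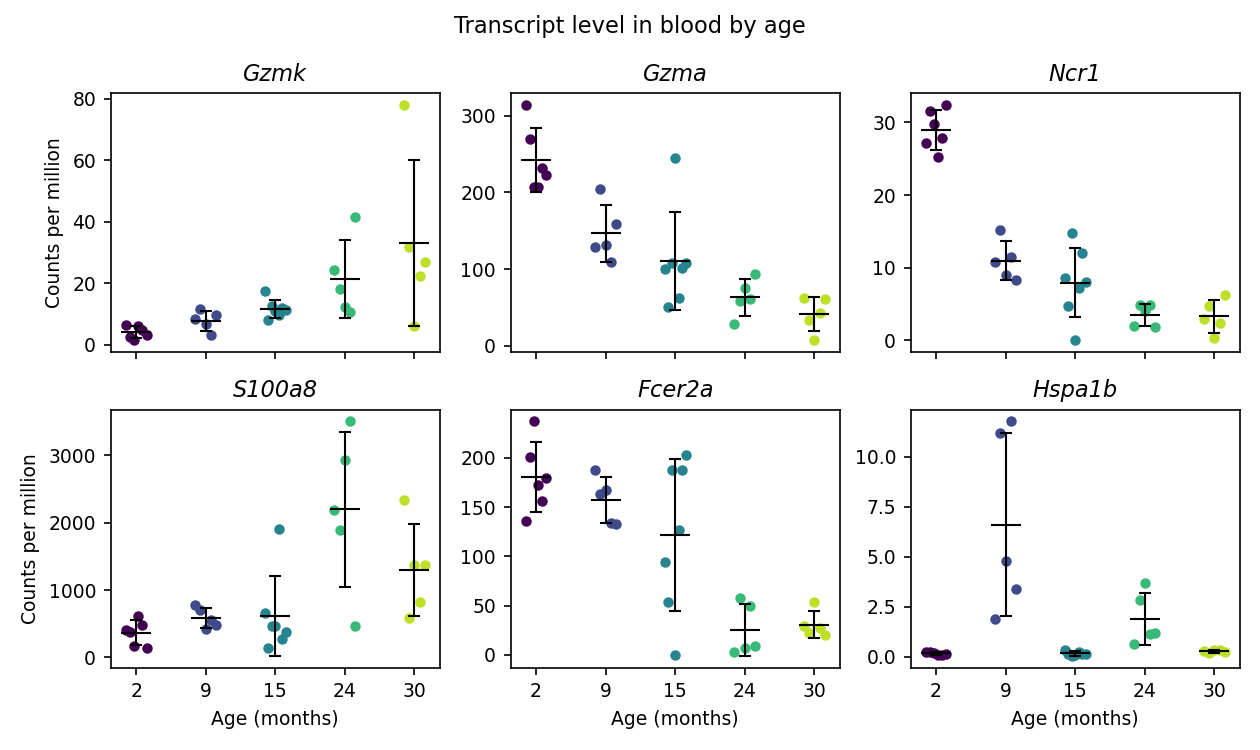
Scaled counts (CPM) of 6 genes in each library at 2, 9, 15, 24 and 30 months; points are libraries, horizontal bars the mean and error bars the SD. Gzma, Ncr1 and Fcer2a have lower means at 30 than at 2 months.

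In the mature neutrophil list 19 of 30 members rose at 30 months and none fell (29 higher adjusted over the list alone), with Stfa2l1 (3.12±0.51), BC100530 (4.64±0.87) and Stfa2 (4.40±0.85), all genes of the stefin A cluster whose near-identical copies can split reads (adjusted p = 6.91e-17, adjusted p = 0.316 with an estimated correlation). S100a8 rose by 1.82±0.53 (adjusted p = 0.0242). Of the neutrophil granule and precursor list 2 of 18 members rose (2, with 1 lower, adjusted over the list alone), Anxa1 (1.32±0.38) and Ltb4r1 (1.55±0.46); the list was not called (adjusted p = 0.0618). The classical monocyte list had 4 of 23 members higher (6 adjusted over the list alone), among them Ly6c2 (1.26±0.28), Ccr2 (1.41±0.32) and Cd14 (1.91±0.49) (adjusted p = 2.42e-06, adjusted p = 0.562 with an estimated correlation). The non-classical monocyte list was not called (adjusted p = 0.335) and 1 of 17 rose, Gngt2 (0.83±0.27; 0.53, adjusted p = 0.161 without 30 months replicate 4), though not adjusted over the list alone. The platelet and megakaryocyte list had 3 of 30 members higher (10 adjusted over the list alone), Gp1bb (2.18±0.59), Itgb3 (1.47±0.42) and Tpm4 (1.20±0.40) (adjusted p = 1.4e-07, adjusted p = 0.611 with an estimated correlation). Eosinophil, basophil and mast cell genes rose in 5 of 21 (7 higher and 1 lower adjusted over the list alone), with Fcer1a (2.36±0.61), Il6 (2.0±0.58) and Mcpt8 (2.58±0.82), but the list was not called (adjusted p = 0.102), and Mcpt8 was at 1.57 (adjusted p = 0.191) without 30 months replicate 5.

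The B cell list had 2 of 24 members lower at 30 months (1 adjusted over the list alone), Btla (-1.30±0.37) and Fcer2a (-2.56±0.83) (adjusted p = 4.37e-05, adjusted p = 0.68 with an estimated correlation). Ms4a1, or CD20, did not pass (-0.78±0.74, adjusted p = 0.511), nor did Ighm (-0.66±0.53, adjusted p = 0.426). In the age-associated B cell list 4 of 17 members rose (5 adjusted over the list alone), S100a6 (2.08±0.44), Cxcr3 (1.66±0.38) and Il10 (5.17±1.5), which T cells and myeloid cells also transcribe (adjusted p = 0.000233, adjusted p = 0.316 with an estimated correlation). The naive lymphocyte list had 5 of 18 members lower (5 adjusted over the list alone), among them Bach2 (-1.48±0.23), S1pr1 (-0.86±0.21) and Als2cl (-1.85±0.51) (adjusted p = 0.00968, adjusted p = 0.563 with an estimated correlation). Helper and regulatory T cell genes fell in 4 of 17 (4 adjusted over the list alone), Izumo1r (-2.26±0.39), Foxp3 (-2.03±0.42) and Cd40lg (-2.66±0.72) (adjusted p = 0.0172, adjusted p = 0.316 with an estimated correlation). The T cell list was not called (adjusted p = 0.888) and 1 of 25 fell, Trat1 (-2.54±0.83), though not adjusted over the list alone; Cd3e (-0.03±0.48) and Cd8a (0.86±0.56) did not pass. Dendritic cell genes were not called (adjusted p = 0.449), with 2 of 20 lower in both counts, Ccr9 (-2.60±0.58) and Pacsin1 (-1.39±0.45). The plasma cell and immunoglobulin constant list was not called (adjusted p = 0.0991): Txndc11 (-0.73±0.15) and Sdc1 (-2.38±0.58) fell and Sec11c (0.80±0.22) rose, as adjusted over the list alone. Of the MHC class II list 2 of 14 fell, as adjusted over the list alone, H2-Ob (-1.40±0.37) and Ciita (-1.42±0.48) (adjusted p = 0.189). Of the MHC class I list 1 of 24 rose, as adjusted over the list alone, H2-D1 (0.76±0.19; adjusted p = 0.0875).

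The antioxidant list had 10 of 27 members higher at 30 months (11 adjusted over the list alone), Txn1 (1.13±0.19), Prdx5 (1.29±0.26) and Gpx4 (1.32±0.35) (adjusted p = 2.09e-06). Glycolysis and hypoxia genes rose in 6 of 27, as adjusted over the list alone, with Pgk1 (1.02±0.16), Tpi1 (1.20±0.20) and Pkm (1.18±0.23) (adjusted p = 0.000225; for both lists adjusted p = 0.362 and 0.253 with an estimated correlation). The nuclear-encoded respiratory chain list had 7 of 94 higher (3 adjusted over the list alone), Ndufs4 (0.72±0.17), Cox6b1 (0.73±0.18) and Cox4i1 (0.67±0.19) (adjusted p = 2.09e-06, adjusted p = 0.563 with an estimated correlation). Of the proteasome list 3 of 34 rose (2 adjusted over the list alone), Psmd13 (0.59±0.13), Psma7 (0.59±0.17) and Psmb5 (0.56±0.18) (adjusted p = 0.00887, adjusted p = 0.736 with an estimated correlation), with Psmb5 at 0.34 (adjusted p = 0.186) without 30 months replicate 4. The cytosolic ribosomal protein list was called higher (adjusted p = 0.0378, adjusted p = 0.776 with an estimated correlation). Yet of 82 members 1 rose, Rpl3l (1.05±0.36), and 1 fell, Rps4l (-1.98±0.58; -2.61, adjusted p = 0.0125 without 30 months replicate 1), neither adjusted over the list alone. Of the sirtuin, DNA methylation and chromatin list 8 of 30 fell (13 adjusted over the list alone), Tet1 (-2.35±0.46), Suz12 (-0.71±0.15) and Setd2 (-0.70±0.18) (adjusted p = 0.000233). The DNA repair list had 6 of 37 lower (8 adjusted over the list alone), Parp1 (-1.04±0.21), Trp53bp1 (-0.96±0.20) and Ercc2 (-0.72±0.19) (adjusted p = 0.000736; for both lists adjusted p = 0.253 and 0.562 with an estimated correlation). Interferon response genes fell in 5 of 50, as adjusted over the list alone, Trim25 (-0.78±0.16), Samd9l (-0.95±0.19) and Ifi203 (-0.79±0.16) (adjusted p = 0.0384). Replication-dependent histone genes, many of them without a poly(A) tail and with near-identical copies, rose in 5 of 26 (8 higher and 1 lower adjusted over the list alone), Hist1h4h (1.88±0.53), Hist1h2be (1.67±0.47) and Hist3h2a (1.38±0.40) (adjusted p = 0.000432; for both lists adjusted p = 0.736 with an estimated correlation). Without the 8 libraries in which 1 V segment held over 50% of a locus the respiratory chain, proteasome, ribosomal, interferon response and glucocorticoid lists were not called.

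Glucocorticoid response genes rose at 30 months in 4 of 15, as adjusted over the list alone, Cebpd (1.71±0.44), Il1r2 (1.87±0.49) and Dusp1 (1.38±0.42) (adjusted p = 0.0384). Tissue macrophage genes rose in 2 of 16 (1 adjusted over the list alone), among them Cfp (1.12±0.38) (adjusted p = 0.032; for both lists adjusted p = 0.562 and 0.736 with an estimated correlation). Of the senescence and p53 target list 3 rose, led by Phlda3 (2.18±0.34), and 2 fell, Sesn1 (-1.45±0.30) and Btg2 (-0.66±0.16) (5 and 2 adjusted over the list alone). The list was not called (adjusted p = 0.179). Cdkn2a, which encodes the senescence marker p16, was at 0.0903 ± 0.0436 and 0.621 ± 0.66 CPM and did not pass (2.75±1.14, adjusted p = 0.0987). It did once 15 months replicate 4 was left out of the fit (2.8, adjusted p = 0.0136) and was at 1.87 (adjusted p = 0.321) without 30 months replicate 2. Inflammatory cytokine genes were not called (adjusted p = 0.347): Il1b (1.86±0.47), Myd88 (0.83±0.23) and Il6 (2.0±0.58) were among 4 higher members and 2 were lower (5 and 5 adjusted over the list alone). Immediate early genes were not called (adjusted p = 0.197), with Ier3 (2.76±0.41) among 4 higher and Dusp2 (-1.24±0.28) and Btg2 (-0.66±0.16) among 3 lower (5 and 4 adjusted over the list alone). The circadian clock list was not called (adjusted p = 0.417): Arntl fell (-0.97±0.17), while Csnk1e (0.94±0.21) and Nfil3 (1.41±0.35) rose (3 higher and 2 lower adjusted over the list alone). Cell cycle genes were not called (adjusted p = 0.182), with Ndc80 (-0.95±0.22) and Aurkb (-0.77±0.26) lower and Dut (0.95±0.22) higher (1 each adjusted over the list alone), and Aurkb held under 4 of 9 settings and in 4 of 12 runs that left out 1 library (adjusted p up to 0.205). Stem and progenitor cell genes were not called (adjusted p = 0.396), with Myb (-1.92±0.40) lower and Spink2 (1.8±0.55) and Gata2 (1.62±0.55) higher (2 lower and 3 higher adjusted over the list alone). Liver transcripts were not called (adjusted p = 0.102), and Hp was the 1 riser in both counts (1.82±0.42).

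The red cell lists were not called at 30 against 2 months. Of the haemoglobin and haem synthesis list Tmem14c alone rose (0.57±0.15), as adjusted over the list alone, and the list had adjusted p = 0.418; Hbb-bs (0.77±0.65) and Alas2 (0.04±0.63) did not pass. The red cell membrane list (adjusted p = 0.253) was not called, nor were the heat shock (adjusted p = 0.16), translation factor (adjusted p = 0.19) and mitochondrially encoded respiratory chain lists (adjusted p = 0.154), none of which had a member past edgeR's test over all genes or over the list alone. Skeletal muscle (adjusted p = 0.628) and stromal transcripts (adjusted p = 0.603) were not called, the latter with a median of -0.10 and a mean of -0.04 where camera pointed up, and Col3a1 lower in both counts (-2.78±0.85). Pf4 was at 1.24±0.58 and did not pass. No list held with an estimated correlation, and 21 of 43 passed with the preset one. The count of 2072 genes ran from 1072 without 30 months replicate 1 to 3393 without 15 months replicate 4. Without the 8 libraries 2489 genes were higher and 2243 lower. Of 105 named calls 72 held in every run that left out 1 library; the 33 that did not include Fcer2a (adjusted p up to 0.0887) and S100a8 (up to 0.087). Leaving out 1 library ended the calls of the helper T cell (30 months replicate 3), proteasome (30 months replicate 4) and 4 other lists (adjusted p up to 0.851).

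Blood at 24 months differed from blood at 2 months in 4079 of 14331 genes by edgeR (2058 higher, 2021 lower). The mature neutrophil, respiratory chain, ribosomal, proteasome and antioxidant lists were called higher by camera and the natural killer, T cell and naive lymphocyte lists lower, with the preset correlation alone. All but the last moved so with 9 and 24 months grouped, where a shared batch stays open for any pair with 1 of these ages. Mitochondrial ribosomal RNA took 5.39 to 7.11% of counts in 4 of 5 libraries of 24 months and 1.99% in replicate 1. The largest rises without overlap were in Avil (4.84±0.96), Apol10b (4.26±0.85), Wwtr1 (4.02±0.63) and Zbtb32 (3.83±1.12), and the largest falls in Klri2 (-3.49±0.61), Ccr9 (-3.18±0.60), Klrc2 (-3.15±0.51) and Klra7 (-3.14±0.58) (log2 ± SE, adjusted p between 9.49e-05 and 0.0128). Avil, Zbtb32 and Chil3 lost their calls without the 8 libraries, and Avil with limma voom (adjusted p up to 0.311, 0.146 and 0.0686). Of the mature neutrophil list 25 of 30 rose (26 adjusted over the list alone), Stfa2l1 (3.12±0.51) and Wfdc17 (3.28±0.56) (adjusted p = 1.25e-14, adjusted p = 0.303 with an estimated correlation), with S100a8 at 2.58±0.54. Natural killer genes fell in 20 of 25 and 1 rose (21 and 1 adjusted over the list alone), Serpinb9b (-2.03±0.30) and Klrk1 (-1.49±0.24) (adjusted p = 3.63e-12). T cell genes fell in 9 of 25 in both counts, Cd5 (-1.84±0.25) and Cd28 (-1.60±0.40) (adjusted p = 4.78e-05, for both lists adjusted p = 0.173 and 0.651 with an estimated correlation). Cd3e fell by 1.39±0.49 (adjusted p = 0.0364), called in 5 of 12 runs without 1 library. Without 24 months replicate 5 Cd3e and Lef1 were at -2.11 and -3.25 (adjusted p = 0.00287 and 0.000208). Naive lymphocyte genes fell in 8 of 18 (8 and 1 higher adjusted over the list alone), S1pr1 (-1.08±0.21) and Lef1 (-2.45±0.54) (adjusted p = 0.000366, adjusted p = 0.334 with an estimated correlation). Helper and regulatory T cell genes fell in 5 of 17 (8 and 2 higher adjusted over the list alone), Izumo1r (-2.5±0.39) and Foxp3 (-2.79±0.44) (adjusted p = 0.00689, adjusted p = 0.173 with an estimated correlation). B cell genes fell in 2 of 24 in both counts, Cr2 (-2.64±0.77) and Fcer2a (-2.86±0.84) (adjusted p = 0.0242, adjusted p = 0.83 with an estimated correlation).

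The nuclear-encoded respiratory chain list had 49 of 94 members higher at 24 than at 2 months (58, and 3 lower, adjusted over the list alone), Ndufb8 (1.16±0.18) and Cox6b1 (1.16±0.18) (adjusted p = 1.46e-13, adjusted p = 0.303 with an estimated correlation). Ribosomal protein genes rose in 37 of 82 and 1 fell (46 and 1 adjusted over the list alone), Rps28 (1.22±0.27) and Rpl38 (1.0±0.23) (adjusted p = 1.11e-08). Proteasome genes rose in 20 of 34 (22 adjusted over the list alone), Psma7 (0.93±0.17) and Psmb5 (0.97±0.18) (adjusted p = 1.96e-07; for both lists adjusted p = 0.651 and 0.538 with an estimated correlation). Translation factors rose in 9 of 35 (8 adjusted over the list alone), Eif3i (0.96±0.24) and Eif5a (0.70±0.20) (adjusted p = 0.00373). Antioxidant genes rose in 14 of 27 (17 adjusted over the list alone), Txn1 (1.55±0.19) and Prdx1 (1.17±0.17) (adjusted p = 6.09e-07; for both lists adjusted p = 0.639 and 0.303 with an estimated correlation). Heat shock genes rose in 11 of 26 (13 adjusted over the list alone), led by the inducible Hsp70 genes Hspa1b (3.43±0.52) and Hspa1a (3.22±0.66), near-identical copies that can split reads (adjusted p = 4.78e-05). The classical monocyte list rose in 8 of 23 (9 adjusted over the list alone), Cd14 (2.79±0.50) and Ccr2 (1.35±0.32) (adjusted p = 0.00023; for both lists adjusted p = 0.293 and 0.651 with an estimated correlation). The platelet list rose in 10 of 30 (11 adjusted over the list alone), Gp1bb (2.70±0.60) and Tpm4 (1.32±0.40) (adjusted p = 0.000366, adjusted p = 0.815 with an estimated correlation). Pf4 rose too (1.70±0.58). The neutrophil granule list rose in 4 of 18 (3 adjusted over the list alone), Chil3 (2.14±0.47) and Anxa1 (1.36±0.38) (adjusted p = 0.0418). Age-associated B cell genes rose in 7 of 17 (9 adjusted over the list alone), S100a6 (2.56±0.45) and Ahnak (1.29±0.33) (adjusted p = 0.0108; for both lists adjusted p = 0.815 and 0.541 with an estimated correlation). Histone genes rose in 7 of 26 in both counts, Hist1h4h (2.28±0.53) and Hist1h2be (1.85±0.47) (adjusted p = 0.000844). Glycolysis genes rose in 8 of 27 with 1 lower (9 and 1 adjusted over the list alone), Tpi1 (1.61±0.20) and Pgk1 (1.16±0.16) (adjusted p = 0.00054; for both lists adjusted p = 0.815 and 0.173 with an estimated correlation). Interferon response genes fell in 8 of 50 in both counts, Ifi203 (-0.90±0.16) and Samd9l (-0.93±0.19) (adjusted p = 0.0498). DNA repair genes fell in 12 of 37 with 1 higher (14 and 1 adjusted over the list alone), Parp1 (-1.16±0.21) and Atm (-1.90±0.40) (adjusted p = 0.0153; for both lists adjusted p = 0.815 and 0.66 with an estimated correlation). Chromatin genes fell in 10 of 30 with 1 higher in both counts, Tet1 (-2.89±0.48) and Dnmt1 (-1.23±0.23) (adjusted p = 0.00261). Liver transcripts rose in 4 of 6 in both counts (adjusted p = 0.016; for both lists adjusted p = 0.293 and 0.334 with an estimated correlation). Among them were Hp (2.14±0.43) and Alb (3.98±1.19), the latter at 22.9 CPM in 24 months replicate 2 against a median of 0.401 in the others and not called without it (2.05, adjusted p = 0.163), or at 6.50 (adjusted p = 0.00217) without 2 months replicate 6. Hbb-bs (0.91±0.65), Alas2 (0.32±0.63), Ms4a1 (0.10±0.72), Cd8a (-0.04±0.56), Ighm (0.04±0.53) and Cdkn2a (2.36±1.13) did not pass, the last called without 15 months replicate 4 (2.42, adjusted p = 0.019). Of 55 named calls 51 held in every run that left out 1 library, Pf4 in 7 of 12. Removing 1 library ended the calls of the B cell (24 months replicate 3) and 2 other lists (adjusted p up to 0.444), removing the 8 libraries those of the age-associated B cell, interferon and translation factor lists, and the haemoglobin covariate those of the neutrophil granule and interferon lists.

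At 9 against 2 months, 480 genes changed by edgeR, 195 higher and 285 lower, or 3877 in a fit over these 2 ages. By camera the heat shock, respiratory chain and ribosomal lists were called higher, and the natural killer, T cell, interferon response and stromal lists lower, with the preset correlation alone (adjusted p = 0.117 to 0.775 with an estimated correlation). Mitochondrial ribosomal RNA took 3.94 to 6.47% of counts in the 9 month libraries. The inducible Hsp70 genes rose most, Hspa1b (5.26±0.54, adjusted p = 4.3e-06) and Hspa1a (5.12±0.67, adjusted p = 9.31e-05). Hspa1b went from 0.173 ± 0.0682 CPM (SD, n = 6) to 6.61 ± 4.57 (SD, n = 5). Without overlap and at 2 or more CPM the rises were Wwtr1 (2.4±0.60), Apol11a (2.4±0.63), Fos (2.17±0.41) and Tm4sf1 (1.98±0.56), and the falls Sparc (-2.70±0.72), Ifi44 (-2.08±0.57), Kif11 (-2.07±0.56) and Gpkow (-1.8±0.29) (adjusted p between 0.00107 and 0.0471). Apol11a and Ifi44 were at 3.09 and -1.58 (adjusted p = 0.0105 and 0.121) without 2 months replicate 5. Kif11 was at -1.15 (adjusted p = 0.194) without 2 months replicate 4. Heat shock genes rose in 6 of 26 (8 adjusted over the list alone; adjusted p = 9.07e-10). Respiratory chain genes rose in 8 of 94 (23 adjusted over the list alone), Cox6b1 (0.77±0.18) and Ndufb8 (0.74±0.18) (adjusted p = 3.21e-14; for both lists adjusted p = 0.117 and 0.462 with an estimated correlation). Ribosomal protein genes rose in 2 of 82 in both counts, Rpl10 (0.45±0.12) and Rpl38 (0.86±0.23) (adjusted p = 3.21e-14). Proteasome genes rose in 1 of 34, Psmb5 (0.65±0.18; 6, with 1 lower, adjusted over the list alone; adjusted p = 8.01e-06; for both lists adjusted p = 0.67 and 0.674 with an estimated correlation). Antioxidant genes rose in 2 of 27 (6 adjusted over the list alone), Prdx1 (0.72±0.16) and Sod1 (0.66±0.17) (adjusted p = 0.000489). Immediate early genes rose in 3 of 23 (4 adjusted over the list alone), Fos and Ier2 (0.83±0.22; adjusted p = 0.00722; for both lists adjusted p = 0.67 with an estimated correlation). Natural killer cell genes fell in 2 of 25 (7 adjusted over the list alone), Serpinb9b (-1.61±0.29) and Prf1 (-1.44±0.33) (adjusted p = 1.29e-06). T cell genes fell in 2 of 25 in both counts, Cd5 (-1.48±0.25) and Cd28 (-1.56±0.40) (adjusted p = 0.000121; for both lists adjusted p = 0.462 and 0.775 with an estimated correlation). Helper and regulatory T cell genes fell in 1 of 17 in both counts, Foxp3 (-1.66±0.42; adjusted p = 0.0258). Interferon response genes fell in 4 of 50 (10, with 1 higher, adjusted over the list alone), Eif2ak2 (-1.33±0.26) and Ifih1 (-1.14±0.25) (adjusted p = 3.36e-06; for both lists adjusted p = 0.462 and 0.67 with an estimated correlation). Cell cycle genes fell in 5 of 49 (8 adjusted over the list alone), Mcm4 (-0.73±0.17) and Aurkb (-1.10±0.26) (adjusted p = 0.00269, adjusted p = 0.818 with an estimated correlation). Stromal transcripts fell in 3 of 15 (7 adjusted over the list alone), Col3a1 (-4.69±0.99) and Cdh5 (-1.82±0.48) (adjusted p = 0.000404, adjusted p = 0.67 with an estimated correlation), with Col3a1 at -5.38 (adjusted p = 0.0124) without 9 months replicate 5. DNA repair was called lower (adjusted p = 0.0435, adjusted p = 0.818 with an estimated correlation) with Atm (-1.43±0.39) down and Polb (0.52±0.13) up (6 and 1 adjusted over the list alone).

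No member passed edgeR's test, over all genes or over the list alone, in 7 further lists called higher at 9 against 2 months, the haemoglobin, red cell membrane, mature neutrophil, platelet, translation factor, histone and liver lists. In that order they had adjusted p = 0.0435, 0.0435, 0.00708, 0.00587, 0.00587, 0.00308 and 0.0435, and adjusted p = 0.818, 0.902, 0.818, 0.818, 0.674, 0.818 and 0.67 with an estimated correlation. None of Hbb-bs (1.07±0.65), Alas2 (0.08±0.63), Ms4a1 (0.32±0.72), Cd3e (-1.05±0.49), Cd8a (-0.27±0.57), S100a8 (0.68±0.52), Pf4 (1.19±0.58), Ighm (0.03±0.53) and Cdkn2a (-0.69±1.43) passed. The count of 480 genes ran from 132 without 9 months replicate 2 to 1.2e+03 (to 2 digits) without 15 months replicate 4. Of 31 named calls 8 held in every such run. Removing 1 library ended the calls of the cell cycle (2 months replicate 4), mature neutrophil and immediate early (9 months replicate 1) and 4 other lists (adjusted p up to 0.232), removing the 8 libraries those of the haemoglobin and DNA repair lists, and the haemoglobin covariate those of the haemoglobin, red cell membrane, platelet, DNA repair, histone and liver lists.

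At 15 against 2 months, 27 genes changed by edgeR, 12 higher and 15 lower, with 2009 at an unadjusted p below 0.05. The natural killer cell list was lower by camera. The rises without overlap were Apol10b (4.44±0.84), Bmpr1a (3.06±0.48), S100a6 (1.95±0.42) and Tmem141 (1.52±0.29) and the falls Syt14 (-2.60±0.54), Adamts14 (-2.06±0.41), Serpinb9b (-2.04±0.26) and Itgae (-1.46±0.28) (adjusted p between 0.000431 and 0.0459). S100a6 was at 1.28 (adjusted p = 0.0601) without 15 months replicate 2, and its call held in 5 of 13 such runs and under 3 of 9 settings (adjusted p up to 0.411). Of the natural killer cell list 1 of 25 fell, Serpinb9b (15 adjusted over the list alone), with a list median of -1.19 (adjusted p = 1.02e-25, adjusted p = 0.00662 with an estimated correlation), the 1 list call of any pair that held. The age-associated B cell list had 1 of 17 higher, S100a6 (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.0143, adjusted p = 0.519 with an estimated correlation). No other list called had a member past edgeR's test over all genes. Called higher were the mature neutrophil, proteasome and senescence lists, with 8, 11 and 5 members higher adjusted over the list alone. In that order they had adjusted p = 2.61e-05, 1.62e-10 and 0.00172, and adjusted p = 0.629, 0.381 and 0.321 with an estimated correlation. Called lower were the neutrophil granule, dendritic cell, stromal, chromatin, naive lymphocyte and tissue macrophage lists, with 5, 3, 5, 2, 1 and 1 members lower adjusted over the list alone. By camera they had adjusted p = 0.0163, 8.39e-08, 4.03e-09, 0.0429, 0.00114 and 0.0176 in that order. With an estimated correlation they were adjusted p = 0.629, 0.322, 0.294, 0.46, 0.42 and 0.629. The stem and progenitor and cytotoxic lists were called lower with 3 members lower and 1 higher each adjusted over the list alone, and the skeletal muscle list with 1 higher. In that order they had adjusted p = 0.000421, 0.0262 and 0.0044, and adjusted p = 0.342, 0.629 and 0.294 with an estimated correlation.

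The MHC class I, respiratory chain, translation factor, heat shock and ribosomal protein lists were also called higher at 15 against 2 months, the last with 1 member lower adjusted over the list alone. By camera they had adjusted p = 0.0176, 7.38e-08, 4.01e-05, 7.45e-05 and 2.49e-06 in that order. With an estimated correlation they were adjusted p = 0.629, 0.46, 0.381, 0.322 and 0.629. Called lower were the haemoglobin, red cell membrane, B cell, platelet and histone lists. In that order they had adjusted p = 0.00915, 8.39e-08, 0.000575, 2.22e-06 and 0.00107, and adjusted p = 0.663, 0.629, 0.629, 0.629 and 0.643 with an estimated correlation. Without the 8 libraries the platelet and histone lists reversed to higher (adjusted p = 0.0149 and 0.0294), and the haemoglobin, red cell, B cell, cytotoxic, neutrophil granule, MHC class I, senescence, stem, ribosomal, translation factor, heat shock and tissue macrophage lists were not called. Leaving out 1 library ended the calls of the age-associated B cell (15 months replicate 2), B cell, platelet and histone (15 months replicate 4), mature neutrophil (15 months replicate 5) and 6 other lists (adjusted p up to 0.821). Cdkn2a lay at 5.03±1.12 with an adjusted p of 0.0518. The library of 15 months replicate 4 held 17.2 CPM against a median of 0.279 in the other 6, and without it the value was 2.78 (adjusted p = 0.104). Hbb-bs (-0.12±0.60), Alas2 (-0.35±0.58), Ms4a1 (0.50±0.67), Cd3e (0.12±0.44), Cd8a (-0.36±0.52), S100a8 (0.74±0.49), Pf4 (-0.44±0.53) and Ighm (0.49±0.49) did not pass. The count of 27 genes ran from 3 without 2 months replicate 6 to 127 without 15 months replicate 6. Of 8 named calls 2 held in every such run. The split was 216 higher and 121 lower with DESeq2, 125 and 112 without the 8 libraries, 61 and 136 with limma voom, 11 and 37 with the haemoglobin covariate and 0 and 2 in a fit over these ages alone.

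Between 9 and 15 months 834 genes changed by edgeR, 568 higher and 266 lower at 15 months. By camera the heat shock and platelet lists were called lower and the interferon response list higher, with the preset correlation alone (adjusted p = 0.852 with an estimated correlation). Mitochondrial ribosomal RNA took 3.94 to 6.47% of counts at 9 months and 0.71 to 4.04% at 15 months. Without overlap, the rises were Apol10b (3.24±0.83), Gbp2 (2.72±0.59), Bmpr1a (2.64±0.50) and Ahcyl2 (2.20±0.55) and the falls Angptl1 (-2.15±0.46), Pdgfa (-1.88±0.53), Fos (-1.76±0.39) and Itgb4 (-1.75±0.45) (adjusted p between 0.00419 and 0.037). Ahcyl2 was at 258 CPM in 15 months replicate 4 against a median of 17.7 in the other 6, and at 0.93 without it (adjusted p = 0.0201). The heat shock list was lower, with 4 of 26 down and 1 up (6 and 1 adjusted over the list alone), Hspa1b (-5.39±0.51) and Hspa1a (-5.14±0.63) (adjusted p = 0.00681). Interferon response genes rose in 6 of 50 and 1 fell (12 and 1 adjusted over the list alone): the kinase Eif2ak2 rose (1.28±0.25) and Trim25 fell (-0.73±0.15; adjusted p = 0.00267; for both lists adjusted p = 0.852 with an estimated correlation). MHC class I genes rose in 3 of 24 (4 adjusted over the list alone), Pdia3 (0.90±0.23) and Tap2 (1.07±0.28) (adjusted p = 0.0342). DNA repair genes rose in 3 of 37 (7 adjusted over the list alone), Mre11a (0.61±0.17) and Wrn (0.95±0.27) (adjusted p = 0.0139; for both lists adjusted p = 0.852 with an estimated correlation). Senescence and p53 target genes rose in 3 of 25 (8 and 1 lower adjusted over the list alone), Polk (1.01±0.23) and Cdkn2a (5.72±1.29) (adjusted p = 0.0317, adjusted p = 0.852 with an estimated correlation). Cdkn2a was 3.48 (adjusted p = 0.0208) without 15 months replicate 4. Mitochondrially encoded respiratory chain genes rose in 1 of 7, mt-Nd5 (1.31±0.39, or 0.96, adjusted p = 0.103 without 15 months replicate 2; 2 adjusted over the list alone; adjusted p = 0.0359, adjusted p = 0.852 with an estimated correlation). Nuclear-encoded ones fell in 4 of 94 (3 adjusted over the list alone), Uqcr11 (-0.84±0.21) and Ndufa4 (-0.92±0.25) (adjusted p = 0.00424). Ribosomal protein genes fell in 1 of 82, Rpl38 (-0.79±0.22), though not adjusted over the list alone (adjusted p = 0.000659; for both lists adjusted p = 0.852 with an estimated correlation). Antioxidant genes fell in 1 of 27, Gpx4 (-1.11±0.33, or -1.21, adjusted p = 0.052 without 9 months replicate 1; 1 lower and 1 higher adjusted over the list alone; adjusted p = 0.00681, adjusted p = 0.852 with an estimated correlation). Immediate early genes fell in 3 of 23 (4 adjusted over the list alone), Fos and Dusp2 (-1.01±0.26; adjusted p = 0.0139, adjusted p = 0.852 with an estimated correlation).

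With no member past edgeR's test over all genes or over the list alone, the T cell list was called higher at 15 against 9 months (adjusted p = 0.0317, adjusted p = 0.852 with an estimated correlation). Called lower in the same way were the haemoglobin, red cell membrane, B cell, natural killer cell, dendritic cell, platelet, MHC class II and histone lists. By camera they had adjusted p = 0.00015, 1.81e-09, 0.00424, 0.0115, 0.0399, 7.7e-10, 0.0485 and 6.95e-08 in that order. With an estimated correlation each had adjusted p = 0.852. Hbb-bs (-1.19±0.62), Alas2 (-0.43±0.61), Ms4a1 (0.17±0.70), Cd3e (1.17±0.48), Cd8a (-0.09±0.54), S100a8 (0.06±0.51), Pf4 (-1.63±0.56) and Ighm (0.45±0.51) did not pass. The 834 genes ran from 202 without 9 months replicate 2 to 1664 without 15 months replicate 1. Of 24 named calls 9 held in every such run. Apol10b, mt-Nd5 and Gpx4 kept their calls under 3 of 9 settings, Ndufa4 under 4 and Cdkn2a under 4 of 8 (adjusted p up to 0.272, 0.262, 0.193, 0.15 and 0.188). Leaving out 1 library ended the calls of the immediate early (9 months replicate 1), interferon response (15 months replicate 1), B cell, senescence and DNA repair (15 months replicate 4) and 6 other lists (adjusted p up to 0.936), and leaving out the 8 libraries those of 12 of 19. The split was 93 higher and 97 lower with the haemoglobin covariate, where 11 of 19 list calls were lost, 830 and 800 without the 8 libraries, 2188 and 1939 with limma voom and 84 and 76 in a fit over these ages alone.

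From 15 to 24 months 3125 genes changed by edgeR, 1439 higher and 1686 lower. By camera the mature neutrophil, platelet, histone, antioxidant and red cell membrane lists were called higher at 24 months and the T cell and DNA repair lists lower, with the preset correlation alone (adjusted p = 0.523 to 0.645 with an estimated correlation). Mitochondrial ribosomal RNA took 0.71 to 4.04% of counts at 15 months and, but for 1 library, 5.39 to 7.11% at 24 months. The rises without overlap were Accsl (2.88±0.51), Adcy5 (2.38±0.47), Pnck (2.30±0.48) and Syt13 (2.30±0.50) and the falls Pcsk1 (-9.21±1.88), Gpkow (-2.04±0.29), Rapgef4 (-2.02±0.31) and Zfp507 (-1.93±0.43) (adjusted p between 0.000129 and 0.00374). Pcsk1 reached 130 CPM in 15 months replicate 4 against a median of 0.217 in the other 6, and its change was -5.87 (adjusted p = 0.00172) without it. Mature neutrophil genes rose in 17 of 30 (20 adjusted over the list alone), Asprv1 (2.03±0.45) and Mcemp1 (1.49±0.34) (adjusted p = 8.28e-11, adjusted p = 0.524 with an estimated correlation). S100a8 rose (1.84±0.51), and without 15 months replicate 5 S100a8 and Cd14 were at 2.47 and 2.41 (adjusted p = 0.00117 and 0.000573). Neutrophil granule genes rose in 7 of 18 (13 adjusted over the list alone), Chil3 (1.95±0.45) and Elane (6.25±1.65), the latter at 27.2 CPM in 24 months replicate 4 against a median of 0.391 in the others and not called without it (2.63, adjusted p = 0.237; for the list, adjusted p = 0.00011, adjusted p = 0.524 with an estimated correlation). Classical monocyte genes rose in 5 of 23 in both counts, Ly6c2 (1.17±0.27) and Cd14 (1.79±0.46) (adjusted p = 4.8e-05, adjusted p = 0.567 with an estimated correlation). Platelet genes rose in 13 of 30 (20 adjusted over the list alone), Gp1bb (2.64±0.56) and Itgb3 (1.72±0.40) (adjusted p = 7.43e-12, adjusted p = 0.524 with an estimated correlation), with Pf4 at 2.14±0.56. Red cell membrane genes rose in 9 of 41 (11 adjusted over the list alone), Epor (2.34±0.48) and Tal1 (1.63±0.46) (adjusted p = 3.17e-06, adjusted p = 0.645 with an estimated correlation). Haemoglobin and haem synthesis genes rose in 4 of 22 (3 adjusted over the list alone), Tmem14c (0.75±0.14) and Abcb6 (1.38±0.42) (adjusted p = 0.00227, adjusted p = 0.659 with an estimated correlation), with Abcb6 at 0.69 (adjusted p = 0.189) without 24 months replicate 2. T cell genes fell in 8 of 25 (9 adjusted over the list alone), Trat1 (-3.63±0.85) and Cd5 (-0.95±0.24) (adjusted p = 0.000833, adjusted p = 0.645 with an estimated correlation). Cd3e fell (-1.51±0.48), or was at -0.82 (adjusted p = 0.118) without 15 months replicate 4 and -2.23 (adjusted p = 0.00301) without 24 months replicate 5. Trat1 was at 58.4 CPM in 15 months replicate 4 against a median of 2.20 in the others, and at -1.35 (adjusted p = 0.0128) without it. Naive lymphocyte genes fell in 5 of 18 and 2 rose (7 and 2 adjusted over the list alone): S1pr1 fell (-0.99±0.20) and Rgs10 rose (1.63±0.46; adjusted p = 0.0412, adjusted p = 0.645 with an estimated correlation). Natural killer cell genes fell in 4 of 25 and 1 rose (7 and 1 adjusted over the list alone), Klrc2 (-1.59±0.47) down and the adaptor Tyrobp (1.20±0.35) up (adjusted p = 0.0412, adjusted p = 0.659 with an estimated correlation).

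Antioxidant genes rose from 15 to 24 months in 13 of 27 (17 adjusted over the list alone), Prdx5 (1.48±0.25) and Gpx4 (1.74±0.34) (adjusted p = 1.44e-07, adjusted p = 0.523 with an estimated correlation). Respiratory chain genes rose in 23 of 94 (24 adjusted over the list alone), Uqcr11 (1.18±0.21) and Cox6b1 (0.94±0.18) (adjusted p = 4.85e-07). Histone genes rose in 11 of 26 (18 adjusted over the list alone), Hist1h4h (2.52±0.51) and Hist1h4i (1.99±0.49) (adjusted p = 5.49e-09; for both lists adjusted p = 0.524 with an estimated correlation). Ribosomal protein genes rose in 8 of 82 and 1 fell (1 higher adjusted over the list alone), Rps28 (0.88±0.25) and Rpl38 (0.94±0.22) (adjusted p = 0.000356). The proteasome list had 1 of 34 higher, Psmb5 (0.59±0.18), though not adjusted over the list alone (adjusted p = 0.0467; for both lists adjusted p = 0.666 and 0.769 with an estimated correlation). Heat shock genes rose in 5 of 26 and 1 fell, as adjusted over the list alone, Hspa1b (3.56±0.49) and Hspa1a (3.25±0.62) (adjusted p = 0.0283). Glycolysis genes rose in 8 of 27 with 1 lower in both counts, Tpi1 (1.29±0.19) and Pkm (1.14±0.22) (adjusted p = 0.00258; for both lists adjusted p = 0.567 and 0.523 with an estimated correlation). Glucocorticoid response genes rose in 4 of 15 in both counts, Cebpd (2.28±0.42) and Mt1 (1.97±0.44) (adjusted p = 0.0283). Tissue macrophage genes rose in 2 of 16 in both counts, Cfp (1.26±0.36) and Hmox1 (1.34±0.39) (adjusted p = 0.00352; for both lists adjusted p = 0.524 and 0.567 with an estimated correlation). Liver transcripts rose in 3 of 6 (4 adjusted over the list alone), Alb (5.22±1.20) and Hp (1.5±0.40) (adjusted p = 0.00574, adjusted p = 0.523 with an estimated correlation), with Alb at 3.28 (adjusted p = 0.0458) without 24 months replicate 2. DNA repair genes fell in 10 of 37 in both counts, Ercc3 (-0.62±0.13) and Lig4 (-1.14±0.26) (adjusted p = 0.00119, adjusted p = 0.524 with an estimated correlation). Chromatin genes fell in 10 of 30 with 1 higher (12 and 1 adjusted over the list alone), Kdm5a (-0.86±0.19) and Kdm6a (-0.68±0.16) (adjusted p = 0.0298, adjusted p = 0.524 with an estimated correlation). Hbb-bs (1.03±0.62), Alas2 (0.67±0.61), Ms4a1 (-0.39±0.71), Cd8a (0.32±0.54), Ighm (-0.44±0.51) and Cdkn2a (-2.66±1.0) did not pass, and Cdkn2a was at -0.36 without 15 months replicate 4. The gene count became 1649 without 24 months replicate 3. It split into 1979 higher and 1546 lower without the 8 libraries, where the chromatin, glucocorticoid and tissue macrophage lists were not called. S100a8, Cd14, Chil3, Ly6c2, Trat1, Kdm6a, Cfp and Hp lost their calls without the 8 libraries and in the fit over these ages (adjusted p up to 0.116, 0.104, 0.347, 0.0686, 0.109, 0.092, 0.148 and 0.114). Of 52 named calls 43 held in every run that left out 1 library. Omitting 1 library ended the calls of the chromatin (15 months replicate 4), haemoglobin (24 months replicate 2) and 5 other lists (adjusted p up to 0.418).

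Between 24 and 30 months 31 genes changed by edgeR, 18 higher and 13 lower, with 1604 at an unadjusted p below 0.05. By camera the T cell and cytotoxic lists were called higher at 30 months and the ribosomal, respiratory chain and heat shock lists lower, with the preset correlation alone (adjusted p = 0.182 to 0.693 with an estimated correlation). The rises without overlap included Sh2d1a (1.49±0.31), Rnf185 (1.02±0.16) and Trp53bp2 (0.97±0.19) and the falls were Tra2a (-1.09±0.22), Nfat5 (-0.88±0.15), Tnip2 (-0.71±0.15) and Vkorc1l1 (-0.67±0.13) (adjusted p between 0.00906 and 0.033). The T cell list had 1 of 25 higher, Cd5 (1.28±0.25; 2 adjusted over the list alone; adjusted p = 1.64e-13, adjusted p = 0.418 with an estimated correlation). The cytotoxic list had no member higher over all genes but 6 adjusted over the list alone (adjusted p = 1.36e-11, adjusted p = 0.182 with an estimated correlation). Ribosomal protein genes fell in 1 of 82 in both counts, Rpl10 (-0.63±0.13; adjusted p = 3.91e-12, adjusted p = 0.693 with an estimated correlation). Heat shock genes fell in 1 of 26, Hspa1b (-2.71±0.53; 9 adjusted over the list alone; adjusted p = 1.84e-07, adjusted p = 0.182 with an estimated correlation). With no member past edgeR's test over all genes, the natural killer, non-classical monocyte, naive lymphocyte, mitochondrially encoded respiratory chain, circadian clock, stromal and basophil lists were called higher. Adjusted over the list alone, 3 natural killer genes and 1 monocyte gene were higher. In that order they had adjusted p = 0.00174, 0.00148, 0.021, 0.0201, 0.0113, 0.00502 and 0.0353, and adjusted p = 0.693, 0.693, 0.693, 0.751, 0.27, 0.693 and 0.905 with an estimated correlation. Lower in that way were the nuclear-encoded respiratory chain, translation factor and proteasome lists, the last with 1 member lower adjusted over the list alone. By camera they had adjusted p = 4.67e-09, 0.00174 and 1.89e-07 in that order. With an estimated correlation each had adjusted p = 0.693. Hbb-bs (-0.13±0.68), Alas2 (-0.28±0.66), Ms4a1 (-0.88±0.76), Cd3e (1.36±0.51), Cd8a (0.91±0.59), S100a8 (-0.76±0.55), Pf4 (-0.46±0.61), Ighm (-0.71±0.55) and Cdkn2a (0.39±1.03) did not pass, and Cd3e was called without 24 months replicate 5 (2.08, adjusted p = 0.0472). The 31 genes ran from 1 without 30 months replicate 5 to 144 without 15 months replicate 4. Of 11 named calls 1 held in every such run. Omitting 1 library ended the calls of the natural killer cell (24 months replicate 1) and 4 other lists (adjusted p up to 0.259), and omitting the 8 libraries those of the naive lymphocyte, natural killer, translation factor and stromal lists. A fit over these ages alone called 0.

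Across all 5 ages, 4603 genes differed, and 3342 had a linear trend with age, 1607 rising and 1735 falling. The steepest rises per 10 months (log2 ± SE) were Gpc6 (2.72±0.57), Trim40 (2.26±0.74), AF067061 (2.01±0.72), Avil (1.90±0.36), Ahnak2 (1.90±0.53) and Chit1 (1.8±0.53). The steepest falls were Klra4 (-1.18±0.18), Klri2 (-1.16±0.17), Ncr1 (-1.14±0.18), Klra1 (-1.09±0.19), Fcer2a (-1.09±0.27) and Ccr9 (-0.97±0.18). In 15 months replicate 2 AF067061, Ahnak2, Chit1 and Trim40 stood far above the other 6 libraries of that age, at 48.9, 26.6, 15.5 and 27.8 CPM, and AF067061 had adjusted p = 0.0527 without 9 months replicate 5. Mature neutrophil genes trended upward in 29 of 30, classical monocyte genes in 12 of 23 (17 adjusted over the list alone), antioxidant genes in 13 of 27, histone genes in 10 of 26 and tissue macrophage genes in 6 of 16. Natural killer cell genes trended downward in 16 of 25 (18 adjusted over the list alone), with 1 upward. B cell genes trended downward in 7 of 24 (10 adjusted over the list alone), naive lymphocyte genes in 7 of 18 (8, with 1 upward, adjusted over the list alone), chromatin genes in 11 of 30 (15, with 1 upward, adjusted over the list alone) and DNA repair genes in 7 of 37. Beyond a straight line, 1463 genes departed. Among the smallest p-values were those of Rnf185 (adjusted p = 4.95e-07), Exoc7 (3.51e-06), Rbl1 (1.95e-05), Dnajb1 (2.27e-05) and Cebpg (2.27e-05), all by edgeR. Among the lists, 16 of 94 respiratory chain, 9 of 50 interferon response, 8 of 26 heat shock, 8 of 82 ribosomal protein and 6 of 15 stromal genes departed. The count of 1463 became 835, 964 and 924 without 9 months replicates 2, 3 and 4 and 2292 without 15 months replicate 1, and the trend count was 738 without the 2 month group. Of the named genes, 10 of 12 trends and 6 of 6 departures held in every run that left out 1 library, but the trends of Trim40, AF067061, Ahnak2, Chit1, Klri2, Ncr1, Fcer2a and Ccr9 were not called without the 2 month group, nor those of the first 4 and Fcer2a over 2, 15 and 30 months.

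The use of V segments, the variable gene parts joined in each B or T cell clone, was narrower in blood at 30 months than at 2 months. The effective number of segments, that of equally used segments with the same concentration, was computed after thinning each library to a common count. For Trbv, the beta chain of the T cell receptor, it was 7.01 ± 5.78 (SD, n = 5) at 30 months and 15.0 ± 0.18 (SD, n = 6) at 2 months (exact 2-sided permutation p = 0.00433, the smallest this design allows, adjusted p = 0.013). All 5 old libraries lay below every young one. For Ighv, the immunoglobulin heavy chain, it was 25.8 ± 17.2 (SD, n = 5) against 44.3 ± 2.27 (SD, n = 6; exact permutation p = 0.00866, adjusted p = 0.013). For Igkv, the kappa light chain, it was 27.4 ± 18.5 (SD, n = 5) against 48.7 ± 0.732 (SD, n = 6; exact permutation p = 0.0173, adjusted p = 0.0173). Of the old libraries 4 of 5 lay below every young one for each of these loci. Adjusted values are over these 3 tests. At 24 months the means were 8.74 ± 5.17 for Trbv, 15.8 ± 20.5 for Ighv and 18.6 ± 22.7 for Igkv (SD, n = 5), and at 9 months 14.7 ± 0.223, 45.1 ± 0.726 and 48.9 ± 0.441 (SD, n = 5), with no test made at these ages. The Ighv and Igkv values leave out 15 months replicate 4, which held 8 Ighv and 21 Igkv counts. Counts of V segments sum over near-identical segments whose reads can be split or lost. Segment names do not give the joined sequence, so clones were not counted.

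**Figure D3:**
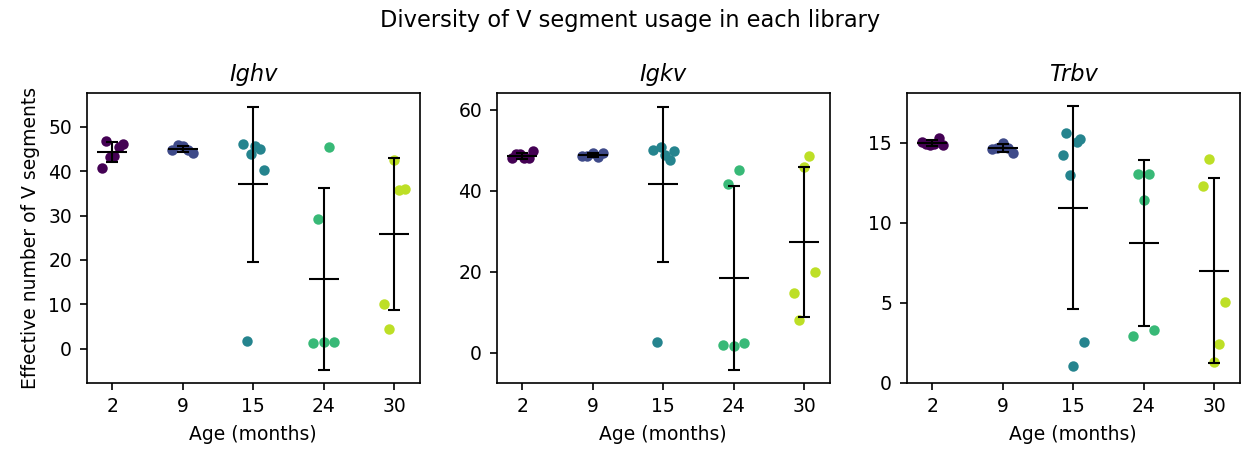
Effective number of Ighv, Igkv and Trbv segments in each library at 2, 9, 15, 24 and 30 months; points are libraries, horizontal bars the mean and error bars the SD. Every library at 2 and 9 months lies at 40.7 or above for Ighv, while 15 months replicate 2 and several libraries at 24 and 30 months lie far below.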

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

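The tests of 15 months replicates 4 and 7 and of the Ighv1-52 segment in the paragraphs below were chosen only after the values were seen. A library counts here as far from its age group when its gap to the nearest other library, divided by the range of the group, passes Dixon's 95% critical value. That held for 65 of 625 groups, where chance gives 31.2. They were 63 of 595 gene groups, 2 of 15 V segment groups and 0 of 15 groups of library measures, and 15 months replicates 2 and 4 held 13 and 8 of them. The gap over the range is in parentheses. Within the libraries of 2 months replicate 1 was highest for Cdkn2a (0.647) and lowest for Trp53bp1 (0.678) and Zbtb32 (0.653). Replicate 2 was lowest for Avil (0.719). Replicate 3 was highest for H2-Ob (0.716), Ighm (0.782) and Pdcd1 (0.701). Replicate 4 was highest for Kif11 (0.868) and Ndc80 (0.672). Replicate 5 was highest for Apol11a (0.918) and Ifi44 (0.778). Replicate 6 was highest for Alb (0.921) and Dnmt1 (0.649). Among the libraries of 9 months replicate 1 was lowest for Gpx4 (0.716). Replicate 5 was highest for Col3a1 (0.863) and lowest for AF067061 (0.719) and Bmpr1a (0.835). Within the libraries of 15 months replicate 1 was highest for Hbb-bs (0.618) and lowest for S1pr1 (0.708). Replicate 2 was highest for AF067061 (0.991), Ahnak2 (0.973), Avil (0.789), Chit1 (0.99), Eif2ak2 (0.782), Gpc6 (0.939), Ighm (0.746), Ms4a1 (0.629), S100a6 (0.752), Trim40 (0.988) and mt-Nd5 (0.7) and lowest for the effective number of Igkv segments (0.936) and the effective number of Ighv segments (0.869). Replicate 4 was highest for Ahcyl2 (0.854), Cd3e (0.724), Cdkn2a (0.914), Dnajb1 (0.628), Pcsk1 (0.913), Pdia3 (0.793), Tap2 (0.788) and Trat1 (0.952). Replicate 5 was highest for Cd14 (0.693) and S100a8 (0.705). Among the libraries of 24 months replicate 1 was highest for Kdm5a (0.746) and Ms4a1 (0.712). Replicate 2 was highest for Abcb6 (0.768), Alb (0.789), Eif5a (0.718), Hbb-bs (0.725) and Rpl38 (0.714). Replicate 4 was highest for Elane (0.961). Replicate 5 was highest for Cd3e (0.886), Cd8a (0.831) and Lef1 (0.755). Within the libraries of 30 months replicate 1 was highest for Pdcd1 (0.754) and Rps4l (0.778). Replicate 2 was highest for Cdkn2a (0.733) and Gpc6 (0.859) and lowest for Nfil3 (0.809). Replicate 3 was highest for Fcer2a (0.717) and Sdc1 (0.763). Replicate 4 was highest for Gngt2 (0.768), Psmb5 (0.764) and Psmd13 (0.792) and lowest for Vkorc1l1 (0.726). Replicate 5 was highest for Mcpt8 (0.794).

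The libraries of 15 months replicates 4 and 7 shared transcripts mostly far lower elsewhere. In replicate 4, 51 genes stood at least 100 times above every library of 2 and 9 months, led by Myo6 and Ly6c1 at 5185 and 2827 CPM without TMM scaling. Replicate 7 held a median of 5.74% of these levels (quartiles 4.44 and 9.21%; Myo6 315, Ly6c1 289), where the highest median in another library was 0.396%. The genes ran from 0.893 to 86.7%, with 64.7% (33 of 51) outside counting error around 1 ratio and 15.7% also over 2-fold from it. Counting error is not all variation, so reads carried at 1 ratio or earlier mixing stay open. RNA of the same T cell clone may stand in both, since replicate 7 was the highest of the other 27 libraries for 3 of the 4 leading receptor segments, and at Traj48 30 months replicate 4 was (0.357 against 0.35); this cannot be told apart from separate clones, and neither a mixed sample nor a shared source was tested.

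The segment Ighv1-52 led the Ighv counts of 3 libraries, 15 months replicate 2, 24 months replicate 5 and 30 months replicate 2, at 792, 149 and 69.8 CPM. In 24 months replicate 5 Ighv1-52, Igkv1-117, Igkv1-122 and Ighj1 stood at 18.8, 19.3, 19.6 and 21.6% of the level in the first, as reads from 1 source would, yet Igkv4-59, at 381 CPM in the first, stood at 0.124% and reached in the 2 others at most 0.00797 of the share that Ighv1-52 did, which argues against carried reads as the only source. In draws by the usage at 2 months 1 heavy segment led as many of 7 libraries in a share of 0.0207, and as many of 10 libraries, with a lower limit, in 0.0627, so that locus alone cannot be told apart from independent draws. Igkv1-117 led the kappa counts of the same 3 libraries (57.9, 62.5 and 32.1%), and 1 pair of leading segments recurred as often in at most 7e-05 of draws of both loci, which argues against independent draws of the 2 loci, though the pair was picked after it was seen. Repeated selection of B cells with this pair may be a candidate explanation, and neither RNA of 1 clone in these libraries, a preference for the pair in young blood nor likeness of sequences was tested.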

How the results depend on the processing

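The fits without the 8 libraries in which 1 V segment held over 50% of a locus (15 months replicates 2, 4 and 7, 24 months replicates 1, 3 and 5, 30 months replicates 3 and 4), the trend over 2, 15 and 30 months, and, for pairs of other ages, the fits without 15 months replicate 4 were chosen only after the data were seen. Called named genes kept their direction under every setting run. Of 304 named calls, 299 held with DESeq2 size factors, 304 with haemoglobin genes removed, 284 with the haemoglobin covariate, 242 without a filter, 298 with limma voom, 282 without the 8 libraries and 175 at a threshold of 0.01. With DESeq2 303 of 303 held, and in a fit over the compared ages alone 203 of 278. Of 141 list calls, 138 held with DESeq2 size factors, 139 with haemoglobin genes removed, 118 with the haemoglobin covariate, 98 without the 8 libraries and 1 with an estimated correlation. At 15 against 2 months without the 8 libraries the platelet and histone lists reversed to higher (adjusted p = 0.0149 and 0.0294). DESeq2 size factors and haemoglobin genes removed left every gene count within 1.5 times its value, and no thinning or the Shannon index left the V segment tests past 0.05. Counts that moved by over 1.5 times are given next, and the cause was not tested except where stated. They do not rank the age steps.

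Without a filter, where edgeR tested 28491 genes, the calls were 160, 10, 1189, 286 and 10 at 9, 15 and 30 against 2, 15 against 9 and 30 against 24 months, and 967 departures. With the haemoglobin covariate they were 48, 190 and 50 genes at 15 against 2, 15 against 9 and 30 against 24 months, and 10 lists at 15 against 9. With an estimated correlation camera called 1 list at 15 against 2 months and 0 in every other pair, where the preset correlation called 14 to 22. At a threshold of 0.01, stricter by construction, the pairs in the order 9, 15, 24 and 30 against 2, 15 against 9, 24 against 15 and 30 against 24 gave 100, 3, 1962, 593, 138, 1104 and 1 genes, with 2057 differing among ages, 1407 trends and 390 departures. DESeq2 gave 1160, 337, 1681 and 240 at 9 and 15 against 2, 15 against 9 and 30 against 24, and 2678 departures. In the order of the 7 pairs limma voom gave 5049, 197, 6635, 5695, 4127, 6206 and 684, with 9969 differing, 5918 trends and 6798 departures. A fit over the compared ages alone gave 3877, 2, 4375, 160, 262 and 0 genes for all pairs but 24 against 2. The 0 stands beside 1604 at an unadjusted p below 0.05 over all ages. Without the 2 month group there were 738 trends and 770 departures, and over 2, 15 and 30 months 1278 trends. Without the 8 libraries there were 3530, 237, 4732, 1630 and 659 genes at 9, 15 and 30 against 2, 15 against 9 and 30 against 24 months, 7763 differing, 5081 trends, 3731 departures and 23 lists at 30 against 24.

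Leaving out each library in turn, the gene counts ran from 132 to 1.2e+03 (to 2 digits, without 15 months replicate 4), 3 to 127, 3076 to 5521, 1072 to 3393, 202 to 1664, 1649 to 4012 and 1 to 144 in the order of the 7 pairs. They ran from 3758 to 6164 for any difference, 2538 to 4453 for trends and 835 to 2292 for departures. The list counts ran from 17 to 23, 20 to 27, 20 to 26, 18 to 22, 11 to 22, 17 to 25 and 12 to 18. Of these runs 3404 of 3933 kept a named call and 1479 of 1625 a list call. Differences in the effective number of segments ran from -26.6 to -16.5 for Igkv (exact permutation p from 0.00952 to 0.0381), -22.7 to -13.2 for Ighv (0.00794 to 0.019) and -9.7 to -6.53 for Trbv (0.00794 to 0.00952). No paired analysis was possible, as the labels share no replicate numbers. A gene with 0 counts in 24 months replicate 2 is known only to lie below 0.265 CPM.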

Other observations

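The grouping of 9 with 24 months, its tests against exon length, GC content and a shared batch were chosen only after the result was seen. The mean of 9 and 24 months differed from that of 2, 15 and 30 months in 2442 genes, 1105 higher and 1337 lower, led by Hspa1b (4.15±0.32), while of 1463 genes departing from a line 1349 (92.2%) lay on the same side of it at 9 and 24 months, against 68.8% of all genes. With DESeq2 size factors 0.968 of these calls (2365) held, which argues against a fault of TMM alone, not both. A heat shock response may take part: with the level of the heat shock list as a covariate 0.163 of the calls outside the list (396 of 2431) held, under the 0.5 that had been written before as a mark of this cause. The reading of that test was changed after it was seen, because 0.754 of the variance of the list's level lay between ages and the median size of change moved little, from 0.58 to 0.53, while its standard error rose from 0.15 to 0.27; the covariate thus cannot be told apart from age, and 15 months replicate 4, at a list level of 5.19, lay within the range of 9 and 24 months (4.84 to 5.36). Transcript length stays open at a Spearman rho of -0.267 across these genes (GC content 0.0442). So does a batch of collection or library making shared by the 2 ages, since no label names 1. Other groupings not of neighbours gave 353, 290, 5 and 0 calls, and 2 with 15 gave 4747. A batch on that split stays open too, for 30 against 2 months and trends.

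Splits of the same libraries into groups of the same sizes were counted, 100 for each result with the real one included. Chance was unlikely at 9 against 2 months (1 split as large, real 480, highest other 19), 24 against 2 (1, 4079, 1587) and 30 against 2 (1, 2072, 1081). So it was for differences among ages (1, 4603, 485), trends (1, 3342, 652) and departures (1, 1463, 266). It stays open at 15 against 9 (3, 834, 2374) and 30 against 24 (4, 31, 52), with shares below 0.05, unadjusted over the 10 results. Other splits called more genes there, and 30 against 24 called 1 gene without 30 months replicate 5 and 0 in a fit over those ages. So it does at 15 against 2 months (5, 27, 45) and 24 against 15 (5, 3125, 5050). What the split with 2374 genes separates was not tested.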
